A study of Mus musculus with 3 samples.

How the data were processed

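RNA was measured in mT3-2D-GFP, a mouse line from a KPC pancreatic tumour (a genetically engineered mouse model) that carries a green fluorescent protein (GFP), and in GFP-positive cells sorted from tumours this line formed in mice. Per the labels, the 3 groups were the cultured line, sorted cells from tumours in SCID mice, which lack T and B cells, and sorted cells from tumours in wild-type (WT) C57BL/6 mice. RNA of 5 SCID tumours and of 6 WT tumours was combined in equal amounts, so each group had 1 library and the spread between tumours was not measured. Libraries were stranded and made from poly(A) RNA with paired reads of 75 bases, and the labels state a mean depth of 40000000 reads per sample. The depth of each library is unknown here, because the table used holds no counts.

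The authors' deposited table holds log2 fold changes between libraries for 17910 RefSeq transcripts, of which 16810 are coding (NM) and 1100 non-coding (NR). Its header does not name the log base; the values were read as log2 because the submitters' processing notes list DESeq2 1.20.0, whose fold changes are on that scale. The notes also list BWA, Partek, R 3.5.1 and the build mm9, with no role or order, and the function that gave the fold changes, any shrinkage and any row filter are not given in the sources used here. The table has a column for SCID against the line, a column for WT against the line and a further column whose name gives only the SCID side. In all 17910 transcripts the third column equalled the first minus the second within 1e-12, so it was read as SCID against WT, and its sign was turned to give WT minus SCID. Values ran from -2.49 to 2.77, a narrow range for log2 ratios of single libraries, so a fold here is a fold on the deposited scale and its relation to a ratio of reads is not known.

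The coordinates were compared with a RefSeq table of GRCm38.p6. Of 17761 transcripts found there, 17363 had the same symbol and 9376 the same start, 99.9% lay on the same chromosome and 86.2% started within 1000 bases, and the stop lay 1 base above the end in 9269. Coordinates printed here are those of the authors' deposited table, 1-based, with the end set to the stop minus 1, and they match GRCm38 although the notes name mm9.

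A gene's value was the mean over its transcripts, a choice made after the table was seen because the planned unit, counts or levels per library, was not what the table held. This gave 11886 genes, 8288 with 1 transcript and 3598 with 2 or more. The mean keeps the 3 comparisons additive. A gene was called higher or lower at 2-fold or more (log2 of 1). With 1 library per group no test between conditions was made and no p-value is given, and no difference has a replicate check. The pooled SD between transcripts of the same gene was 0.22 for WT minus SCID, 0.33 for SCID minus the line and 0.31 for WT minus the line, which describes the spread of transcripts and not of animals.

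Before the data were examined, 38 gene lists, the rule for named genes, the threshold and a set of alternatives were fixed. Genes were matched by exact symbol. For each list with 2 or more genes measured, the median was ranked among the medians of 10000 random lists of the same size (seed 20), and a list was called higher or lower above percentile 97.5 or below 2.5. The percentile describes these libraries and tests no condition. Matching on expression level was planned but needs levels, so random lists were drawn from all genes, and matched on the number of transcripts as an alternative. The named genes are, in each comparison, the 8 highest and the 8 lowest with a described symbol, the 2 highest and 2 lowest past 2-fold in each list (or the 2 farthest from 0 where none passed), and 15 fixed names of which 14 were measured; Ptprc had no value, and some genes the rule names are not reported here. The floors on expression in that rule could not be applied. Other genes named were chosen after their values were seen.

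The planned scaling alternatives, pseudocounts, filters on low values, removal of the 50 most abundant genes, counting intervals and floors on the mean count were not run, since they need counts or levels. Alternatives that were run were centring on the median gene, leaving out marker genes of other cell types, leaving out each list's farthest member and a 4-fold threshold, and, chosen after the table was seen, the median or the most extreme transcript per gene, each transcript alone, genes with 1 transcript, coding transcripts, a 1.5-fold threshold and removal of a quadratic trend in GC content and log10 transcript length. Sequences from GENCODE vM21 gave GC content and length for 16697 transcripts (93.2%). Families of genes that share a symbol stem were described after the table was seen. A panel of 90 myeloid genes was also written after the macrophage genes had been seen to differ, leaving out genes recalled from the highest values, although some values of related families had been seen; it replaced a first check on the 4 measured members of the macrophage list, which was set aside because it ran on the same genes that showed the pattern.

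Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The list ranking was tested on simulated data over 11886 genes with 60 lists per setting. Lists of 20 genes shifted by 0.25 were called in 100% of draws for WT minus SCID, 51.7% for SCID minus the line and 55% for WT minus the line, and lists without a shift in 1.67%, 1.67% and 10%. Lists of 5 genes, nearer in size to the marker and chemokine lists, were called at that shift in 96.7%, 15% and 23.3%. The simulated lists were random genes, so these rates need not hold for lists of related genes that vary together. Of 31 ranked lists, 11 were called higher and 4 lower for WT minus SCID. The counts were 14 and 7 for SCID minus the line and 16 and 5 for WT minus the line. No column of per-sample values was left unmapped.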

Results

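The data are the authors' fold changes between 3 RNA-seq libraries: the cultured mT3-2D-GFP line and GFP-positive tumour cells sorted from SCID and from WT mice, 1 library per group, with 5 and 6 tumours pooled. The design asks how the tumour cells differ when grown with or without T and B cells, and how each differs from culture. All gene values below come from the authors' deposited table, on its log2 scale, as the mean over a gene's transcripts. There are no replicates, so no difference was tested, and the depth of each library is unknown.

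The pool of cells sorted from WT tumours had higher RNA of macrophage-associated, interferon-gamma and MHC class I genes than the pool from SCID tumours. The highest value was that of Ccl9, a chemokine made by myeloid cells, at 1.88 (3.67-fold), followed by H2-DMb1, a chaperone subunit of MHC class II loading, at 1.80, Cfp (properdin) at 1.78, Fcrls at 1.77 and Apoe (apolipoprotein E) at 1.75. P2ry6, a receptor for UDP, was at 1.56, Dok2, an adaptor of haematopoietic signalling, at 1.54 and Arg1 (arginase) was 2.83-fold higher. In all, 36 of 11886 genes were higher in WT by 2-fold or more and 2 were lower. The authors' deposited table places Ccl9 (NM_011338) on chromosome 11 from 83572917 to 83578636 and Apoe (NM_009696) on chromosome 7 from 19696244 to 19699188, both on the reverse strand.

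The 2 genes lower by 2-fold were Ddx3y, a Y-linked RNA helicase, at -1.02 and Itm2a, a membrane protein gene, at -1.02; after removal of a trend in GC content and length, 0 genes passed. Uty and Kdm5d, a pair of Y-linked genes related to histone demethylases, followed at -0.96 and -0.89. Ddx3y lies on chromosome Y from 1260715 to 1286613, Uty from 1097144 to 1245759 and Kdm5d from 897788 to 943811. The next lowest were Gzme, a granzyme, at -0.79, Tagln, an actin-binding protein of contractile cells, at -0.75, Col1a1 (type I collagen) at -0.71 and Mttp, a lipid transfer protein, at -0.69.

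Of 27 listed interferon-gamma response genes 11 were measured. All 11 were above 0 in WT against SCID and 2 passed 2-fold: Igtp at 1.24 and Gbp9 at 1.15, both interferon-inducible GTPases. Any row filter behind the missing genes is unknown, so the shares given for each list describe its measured genes only. Cd274, encoding the checkpoint ligand PD-L1, was at 0.87. The checkpoint and immunosuppressive list, which holds Cd274 and Arg1, was not called. Its median was 0.04 (percentile 86.7), with 10 of 16 measured genes above 0. The interferon-gamma list median was 0.70, at percentile 100 of random lists. The MHC class I list had 13 of 20 genes measured, with 9 of the 13 above 0 and a median of 0.38, also at percentile 100. H2-K1 at 1.21 and H2-D1 at 1.10, the classical class I heavy chains, passed 2-fold, and B2m, their light chain, was at 0.58. H2 class I genes share sequence with one another, so reads could be split between them in a way the table does not show. Among the 11 measured of 30 type I interferon-stimulated genes, 9 were above 0 with a median of 0.28 (percentile 100), and Parp14 at 1.03 passed 2-fold.

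Macrophage and monocyte markers were higher in the WT pool alongside these groups. All 4 measured of the 24 listed were above 0, with Apoe at 1.75, Cd68 at 1.26, Mrc1 at 0.82 and Cd14 at 0.80, and the median was 1.04 (percentile 100). Markers of other host cells gave smaller medians. The median was -0.06 for 4 of 19 fibroblast markers (percentile 14.4). After the GC and length adjustment it was -0.12 at percentile 2.24, and so called lower. These 4 lay on both sides of 0, with Col1a1 at -0.71 and Ly6c1 at 0.41. Of 16 collagens, a family chosen after the table was seen, 6 were above 0 with a median of -0.14 (percentile 0.01). A difference in host fibroblasts between the pools cannot be told apart here from a change in the tumour cells. The median was 0.09 for 4 of 16 endothelial markers (percentile 89.6) and -0.01 for Foxp3 and Tcf7, the 2 T cell markers measured (percentile 41.8). Eomes, of the NK cell list, was at -0.02, Zbtb46, of the dendritic cell list, at -0.07 and Itga2b, of the platelet list, at 0.23. After the GC and length adjustment the T cell median was -0.06 (percentile 21.1), Eomes was at -0.06 and Zbtb46 at -0.11. With the extreme transcript Zbtb46 was at -0.21. No gene of the B cell, neutrophil or islet lists had a value. Only 2 of 21 T cell, 1 of 16 NK cell and 1 of 12 dendritic cell markers were measured. These values therefore cannot show that other host immune cells did not differ.

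Smaller differences appeared in further lists, with no member past 2-fold unless named. NF-kB targets had 15 of 17 genes above 0 and a median of 0.20 (percentile 100), with Icam1 at 0.53 and Vcam1 at 0.51. Of the 5 measured of 23 chemokines, Ccl9 passed 2-fold. The chemokine median of 0.17 was at percentile 98.9, and at percentile 90.4 without Ccl9. Basal-like genes had a median of 0.25 (percentile 99.98; Krt14 at 0.53), epithelial genes 0.13 (percentile 99.97; Spint1 at 0.71, St14 at 0.42), cholesterol synthesis genes 0.11 (percentile 99.98; Mvd at 0.41, or 0.19 on its coding transcript), cell cycle genes 0.10 (percentile 99.98; Aurkb at 0.22) and death receptor genes 0.09 (percentile 99.6; Ripk3, the necroptosis kinase, at 0.78). Lower in WT were the hypoxia list, with 2 of 19 genes above 0 and a median of -0.11 (percentile 0.04; Ero1l at -0.29, Bnip3 at -0.25, or -0.16 after the GC and length adjustment), the immediate-early list at -0.09 (percentile 0.15), the mesenchymal list at -0.09 (percentile 0.58; Sparc at -0.54) and the RAS-ERK list at -0.06 (percentile 1.48). Without the farthest member the mesenchymal list stood at percentile 2.57 and the RAS-ERK list at 3.06, inside the middle range. Not called were cytokines at 0.04, classical genes at 0.02, glycolysis at -0.01, oxidative phosphorylation at 0.01 and the serine and ATF4 list at 0.06. ER stress genes at 0.03, p53 targets at -0.03, acinar markers at -0.12, mesothelial markers at 0.08 and housekeeping genes at 0.02 were not called either. TGF-beta targets at -0.002 and matrix genes at -0.02 were called lower only after the GC and length adjustment. The mesenchymal median was -0.15 after the GC and length adjustment and -0.05 with each transcript counted, the death receptor median 0.05 with each transcript counted, the chemokine median 0.32 after it, 0.09 without Ccl9 or among genes with 1 transcript and 0.59 with each transcript counted, and the NF-kB median 0.31 with the extreme transcript of each gene. The epithelial genes Epcam at 0.34, Cdh1 at 0.17 and Krt19 at 0.06, with Vim at 0.11, Mki67 at 0.18, Trp53 at 0.06, Cdkn2a at -0.04 and Prkdc, the gene mutated in SCID mice, at -0.02, stayed within 2-fold. After the GC and length adjustment Vim was at 0.07, Krt19 at 0.01, Trp53 at 0.02, Cdkn2a at -0.08 and Prkdc at 0.06, on the other side of 0. Across transcripts, which are not independent replicates, WT minus SCID had a Spearman correlation of 0.317 with GC content, and GC content and length together explained 7.02% of its variance.

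**Figure D1:**
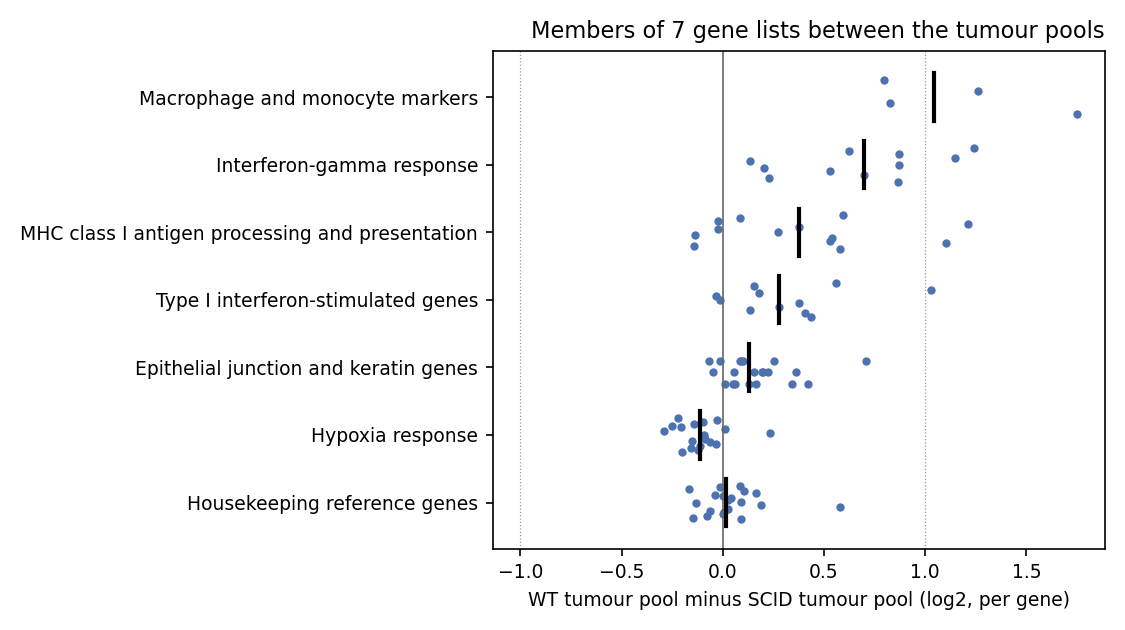
Each point is a gene of the named list, placed by WT pool minus SCID pool (log2, mean over transcripts); black bars are list medians and dotted lines mark 2-fold. The macrophage median lies at 1.04 and the interferon-gamma median at 0.70, while the housekeeping median lies at 0.02.

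The cells sorted from SCID tumours differed from the cultured line in many more genes, with 434 higher and 312 lower by 2-fold or more. Collagens and other matrix genes stood highest: Col1a1 at 2.61, Col6a3 at 2.49, Col5a1 at 2.43, Has2, a hyaluronan synthase, at 2.25, Serpinh1, a collagen chaperone, at 2.22 and Tnc (tenascin C) at 2.20. Atf3, a stress-induced transcription factor, was at 2.22 and Rgs2 at 2.16. The lowest were S100a7a at -2.49, Tmigd1 at -2.14 and Mettl7b at -2.06, then the histone genes Hist2h3c2 at -2.02, Hist2h3c1 at -1.97, Hist1h3g at -1.96 and Hist1h1d at -1.94, and Apoc2, an apolipoprotein, at -1.94. Col1a1 lies on chromosome 11 from 94936224 to 94953042 and S100a7a on chromosome 3 from 90654302 to 90658130.

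Proliferation genes were lower in the SCID pool than in culture. All 30 cell cycle genes were below 0 and 20 were lower by 2-fold, with a median of -1.18 (percentile 0); Rrm2, a ribonucleotide reductase subunit, was at -1.82, Aurkb at -1.60 and Mki67, the gene of the Ki-67 antigen, at -1.33. Genes of cholesterol synthesis had a median of -0.55 (percentile 0), with Fdps at -0.89, and 22 of 22 oxidative phosphorylation genes were below 0 with a median of -0.39 (percentile 0.02; Cycs at -0.76). The serine and ATF4 list had a median of -0.60 (percentile 0) with members on both sides. Mthfd2 at -1.79 and Asns at -1.67, enzymes of one-carbon metabolism and asparagine synthesis, were lower, and Atf3 and Vldlr, at 1.21, were higher.

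Stress, hypoxia and matrix lists were higher in the SCID pool than in culture. Of 23 immediate-early and dissociation genes, 12 were higher by 2-fold with a median of 1.14 (percentile 100), led by Atf3 and by Fosb at 2.15. The tumour cells had been sorted from tissue and the labels describe no such step for the cultured line, so this list and its neighbours differ together with sample handling. Hypoxia genes had 7 of 19 higher by 2-fold and a median of 0.75 (percentile 100), with Ddit4 at 1.60 and Bnip3 at 1.58. Matrix genes had 6 of 14 higher (median 0.65), mesenchymal genes 5 of 15 (0.67; Tagln at 1.83) and TGF-beta targets 5 of 21 (0.62; Fn1, fibronectin, at 1.82), each at percentile 100. Beside these groups, 4 fibroblast markers, Col1a1 among them, had a median of 1.12 and 4 endothelial markers 1.17. Host fibroblasts or endothelial cells carried through the sort cannot be told apart here from a change in the tumour cells. Col1a1 is in the matrix, TGF-beta and fibroblast lists, and Fn1 in the mesenchymal and TGF-beta lists. Their percentiles are therefore not separate results. Of 9 cytokines, 5 were higher and Il1rn, at -1.02, was lower; Csf2, encoding GM-CSF, was at 1.85, Spp1 at 1.37 and the median at 1.02 (percentile 100). The checkpoint and immunosuppressive list had 5 of 16 higher, with Tgfb3 at 1.27 and Ptges at 1.25 (median 0.54, percentile 99.99).

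Epithelial identity genes differed in direction. The epithelial list had a median of -0.36 (percentile 0.12), with Krt7 at -1.18 and Krt19 at -1.01 lower while Epcam at 1.25 and Cldn4 at 1.01 were higher. Cdh1 was at -0.36 and Vim at -0.11, or -0.05 after the GC and length adjustment. Among classical subtype genes (median -0.30, percentile 1.04), Lgals4 was at -1.62, Cdx2 at -1.30, and Onecut2 was 2.30-fold higher. Interferon-gamma genes had a median of 0.41 (percentile 99.5; Irgm2 at 1.04), type I genes 0.32 (percentile 97.9; Parp14 at 1.33), NF-kB targets 0.29 (percentile 98.8; Vcam1 at 1.22) and RAS-ERK genes 0.22 (percentile 97.7; Dusp4 at 0.99). The type I list stood at percentile 85.7, the NF-kB list at 96.0 and the RAS-ERK list at 93.5 without the farthest member, and the type I and NF-kB lists at 96.3 and 94.9 after the GC and length adjustment. MHC class I genes had a median of 0.09 (percentile 77.4), with B2m at 0.77, Tapbp at 0.61 and H2-K1 at -0.46. Markers of host cells stood higher too: the fibroblast list was at percentile 99.97 (Has1 at 1.61), the endothelial list at 99.98 (Flt1 at 1.63) and 4 macrophage markers at a median of 0.70 (percentile 99.4; Apoe at 1.02). Mesothelial markers were instead lower at -0.66 (percentile 0.53; Upk1b at -1.56). The cultured line thus had RNA of these genes, so the mesothelial list does not mark host cells alone. Without the farthest member the fibroblast, macrophage and mesothelial lists stood at percentiles 97.2, 91.5 and 3.29. List medians that moved by over 1.5 times were 0.38 for matrix genes after the GC and length adjustment, -0.36 for the serine and ATF4 list and 0.63 for fibroblast markers with each transcript counted, 0.65 for interferon-gamma and -0.47 for classical genes with the extreme transcript, and 0.16, 0.41 and 0.63 for type I genes, macrophage and fibroblast markers without the farthest member. The basal-like list at 0.35, p53 targets at 0.14 (Trp53inp1 at 1.88, Btg2 at 1.66, Gtse1 at -1.24), chemokines at 0.17 (Cxcl5 at 1.10), acinar markers at 0.75 (percentile 96.9; 98.0, and so called higher, after the GC and length adjustment), T cell markers at 0.23, glycolysis at 0.05, death receptor genes at -0.17, ER stress genes at -0.04 (Dnajb9 at 1.35) and housekeeping genes at -0.16 lay within the middle range of random lists.

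The cells sorted from WT tumours differed from the cultured line in 490 genes that were higher and 241 that were lower by 2-fold. The highest were Apoe at 2.77, Cfp at 2.71, Emilin2 at 2.64, Ccl9 at 2.60, Fcrls at 2.42, Parp14 at 2.36, Cd68 at 2.25 and Rassf2 at 2.22. The lowest were S100a7a at -2.44, Tmigd1 at -2.23 and Mettl7b at -2.03, with the histone genes Hist1h3g at -2.09, Hist2h3c2 at -2.06, Hist1h4f at -1.98, Hist2h4 at -1.96 and Hist2h3c1 at -1.92. Interferon-gamma genes had 6 of 11 higher by 2-fold and a median of 1.05 (percentile 100), with Igtp at 2.13, Irgm2 at 1.91 and Cd274 at 1.28. MHC class I genes had a median of 0.33 (percentile 98.9), with B2m at 1.35, H2-K1 at 0.75 and Tapbp 2.30-fold higher, and type I genes 0.64 (percentile 99.96; Ifih1 at 1.16).

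In the WT pool against the line, cell cycle genes had a median of -1.07 with 19 of 30 lower by 2-fold (percentile 0; Rrm2 at -1.86, Ccnb1 at -1.53, Mki67 at -1.15), and 13 of 23 immediate-early genes were higher with a median of 1.15 (percentile 100; Hspa1a at 2.04, Fosb at 1.96). Hypoxia genes had a median of 0.65 (Bnip3 at 1.33, and Ddit4 2.83-fold higher), mesenchymal genes 0.71 (Tnc at 2.15, Fn1 at 1.82), matrix genes 0.66 (Col1a1 at 1.90, Col6a3 at 1.85), TGF-beta targets 0.56, cytokines 1.02 (Tnf at 1.68, Csf2 at 1.48) and the checkpoint list 0.68 (Arg1 at 2.22, Nt5e at 1.40), each at percentile 100. Chemokines had a median of 0.88 (percentile 99.8; 97.3 without Ccl9), basal-like genes 0.55 (percentile 99.4; Lama3 at 2.11) and NF-kB targets 0.45 (percentile 99.94; Vcam1 at 1.74). Lower lists were cholesterol synthesis at -0.43 (percentile 0; Idi1 at -0.80), oxidative phosphorylation at -0.38 (percentile 0.03) and the serine and ATF4 list at -0.35 (percentile 0.09; Mthfd2 at -1.73, Asns at -1.62). Epcam was at 1.59, Krt19 at -0.95, Cdh1 at -0.19 and Vim at 0.00, and the epithelial list at -0.21 (percentile 3.23) and the classical list at -0.11 (percentile 22.1) were not called. Macrophage markers had a median of 1.73 and fibroblast and endothelial markers 1.30 and 1.23, beside the groups above, while mesothelial markers were at -0.67 (percentile 0.40; 6.12 without Upk1b). Host cells carried through the sort cannot be told apart from tumour cells here either. RAS-ERK genes at 0.13, p53 targets at 0.11, acinar markers at 0.63, T cell markers at 0.22, glycolysis at -0.07, death receptor genes at -0.03, ER stress genes at -0.06 and housekeeping genes at -0.19 were not called. After the GC and length adjustment the basal-like list was no longer called (median 0.28, percentile 93.9), and the medians were 0.32 for matrix genes and -0.22 for oxidative phosphorylation. Counting each transcript gave 0.39 for type I genes, 0.38 for the checkpoint list and 1.09 for mesenchymal genes, and leaving out the farthest member gave 0.50 for chemokines and -0.44 for mesothelial markers.

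**Figure D2:**
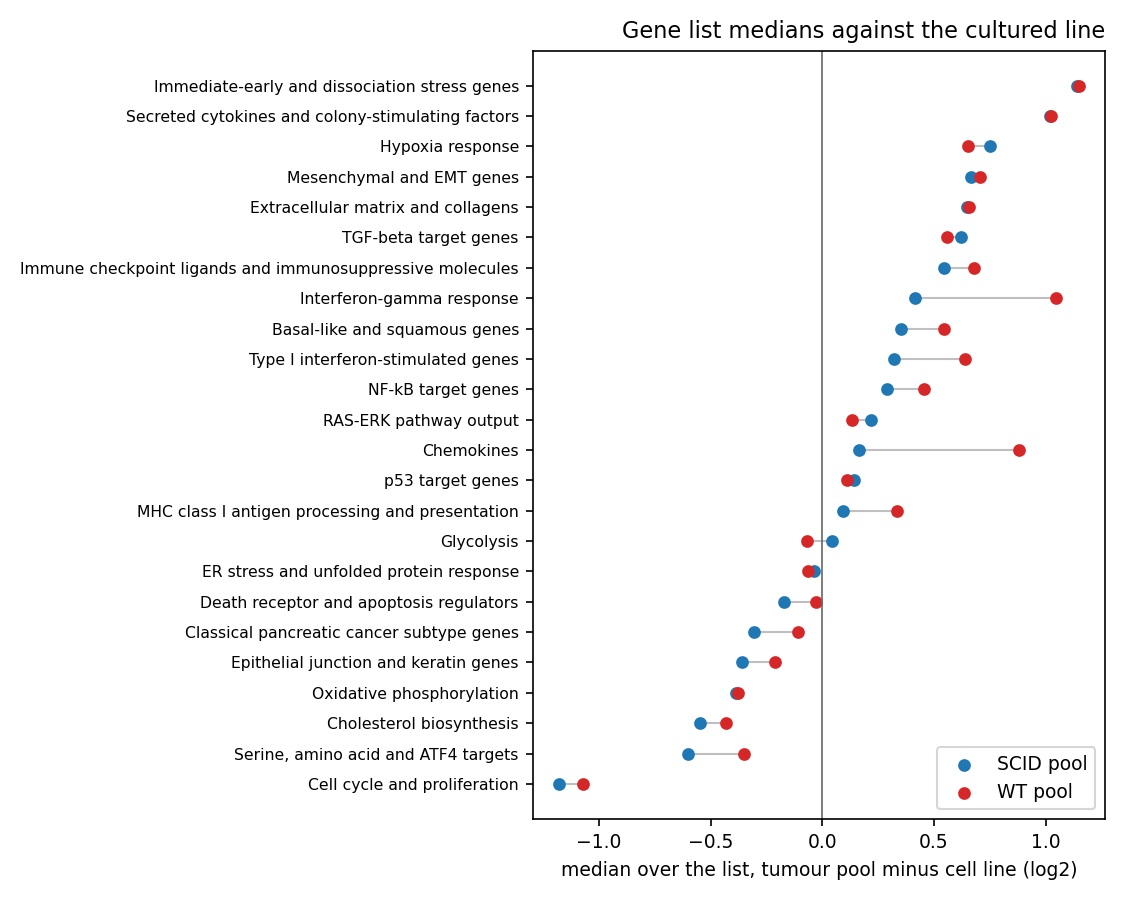
Median of each gene list with 5 or more measured genes, except the housekeeping list, which is not drawn. Values are tumour pool minus cultured line (log2), with the SCID pool in blue and the WT pool in red. The cell cycle list is lowest in both pools, at -1.18 and -1.07, and the interferon-gamma list lies at 0.41 in SCID and 1.05 in WT.

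Of the genes past 2-fold against the line, 352 were higher in both pools and 230 lower in both, and none went in opposite directions past 2-fold. Independent lists of these sizes would share 17.9 and 6.33 genes. Across genes, which are not independent replicates, the fold changes had a correlation of 0.945, a covariance of 0.249 and the same sign in 90.3% of genes; simulated pools without any effect that reuse the line gave 0.501, 0.0146 and 66.6%, with 8.57 genes past 2-fold in both against 582 observed. The simulated noise of every library was drawn from the WT minus SCID differences, because the planned counting noise needs counts. The line was thus taken to be no noisier than the tumour pools, and the simulated correlation follows from reusing it. Noise or handling particular to the line library is not simulated. The single line library could not be split, so part of the excess may come from the shared control. Of the 36 genes higher in WT than SCID, 29 were above the line by 2-fold in WT and 3 in SCID, while 28 were above 0 in SCID against the line.

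**Figure D3:**
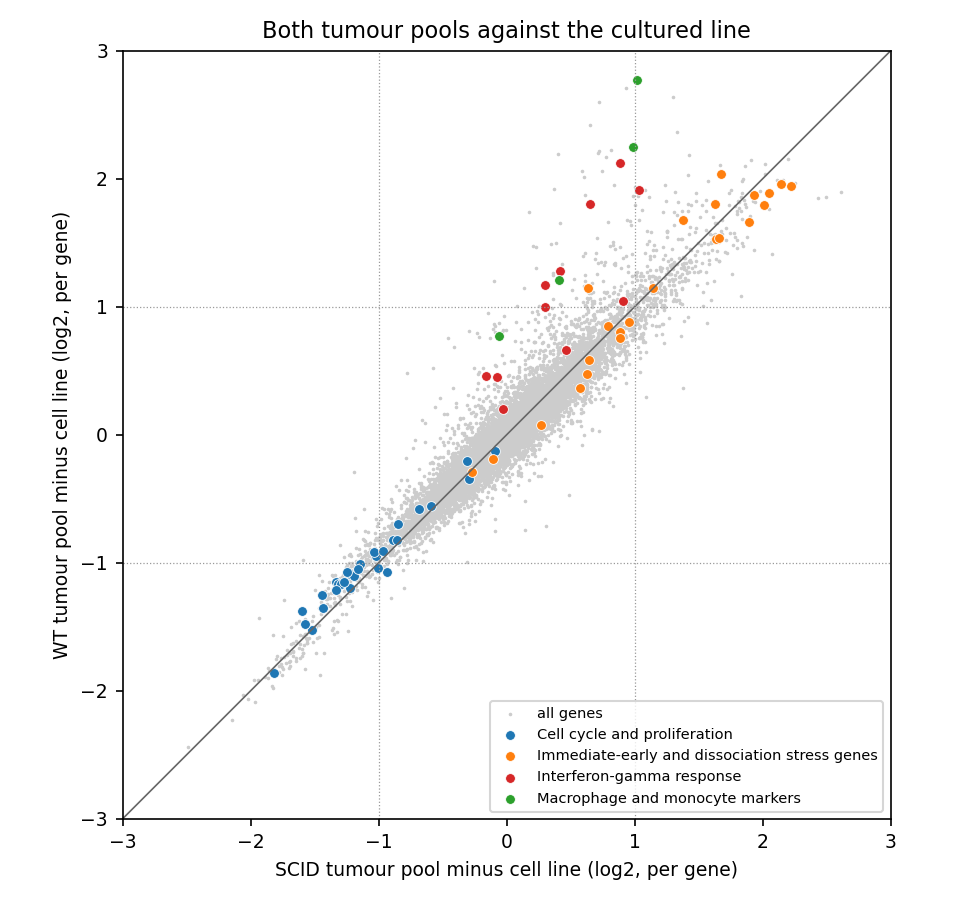
Each point is a gene, with SCID pool minus line on the horizontal axis and WT pool minus line on the vertical axis (log2); dotted lines mark 2-fold and the diagonal marks equal values. Cell cycle genes lie at the lower left in both pools, and the macrophage genes, such as Apoe at 1.02 and 2.77, lie above the diagonal.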

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

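The tests of the myeloid panel, of epithelial genes against a lower share of tumour cells and against dilution, of GC content for the Y-linked genes and of poly(A) capture were chosen only after the results were seen. In 9 named genes the 2 tumour pools lay on opposite sides of the cultured line and differed by 1.5-fold or more; with 1 library per group that difference was not tested. They were Ddx3y (-1.02 in WT against SCID), Uty (-0.96), Kdm5d (-0.89), H2-K1 (1.21), H2-D1 (1.10), Spint1 (0.71), Slc7a11 (0.73), Ripk3 (0.78) and Mrc1 (0.82). Against the line, H2-K1 was at -0.46 in SCID and 0.75 in WT, Ripk3 at -0.56 and 0.22, Slc7a11 at -0.64 and 0.09, Spint1 at -0.22 and 0.49 and Mrc1 at -0.06 and 0.77.

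Macrophage and interferon-gamma genes were both higher in WT. A much lower share of tumour cells in the WT pool would lower epithelial genes, but the epithelial median was 0.13 with quartiles of 0.06 and 0.23. A small share of host cells would lower these genes only slightly, which this list cannot show. The check also takes other host cells to be equal in both pools, which was not shown. Removal of the trend in GC content and length left the interferon-gamma median at 0.66 against 0.70. Host macrophages or monocytes carried through the GFP sort may contribute, although a complete sort would remove those without GFP. In a second panel sharing no gene with the fixed lists, 14 of 90 genes were measured. Of these 12 were above 0, none passed 2-fold and the median was 0.41. However, the panel was drawn up after the pattern was seen and replaced a check on the macrophage list's own 4 genes. Apoe (1.75) and Cd68 (1.26) are abundant macrophage transcripts, while Lyz2, Tyrobp and C1qa had no value here. The presence of T and B cells in the WT hosts, the difference the design names, remains open and untested, as H2-K1 below the line in SCID and above it in WT does not separate tumour cells from host cells.

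The 3 Y-linked genes with values, Ddx3y, Uty and Kdm5d, ranked 1, 3 and 4 from the lowest of 11886 genes in WT against SCID. Dilution by cells without a Y chromosome would lower tumour genes alike, but the lowest epithelial gene was at -0.0698, above Kdm5d at -0.89. Reads moving to X-linked copies would raise those. Kdm5c, Kdm6a and Ddx3x, the copies of the 3 genes, were at 0.02, -0.10 and -0.13. The median with Eif2s3x and Usp9x, copies of Y-linked genes without a value here, was -0.10. The table holds no levels, so a small rise in a more abundant copy would not show, and this check cannot decide. Removal of the trend in GC content and length left the Y-linked median at -0.83 against -0.96. Against the line Ddx3y, Uty and Kdm5d were higher in SCID (0.31, 0.48 and 0.15) and lower in WT (-0.71, -0.47 and -0.74). The difference between the hosts that the design names remains open and untested. Host cells with a Y chromosome in the SCID pool remain open only for the values above the line in SCID. They would not lower the WT pool below the line. The sex of the hosts is not given in the sources used here.

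Cell cycle and histone genes were lower in both tumour pools than in culture, and 64 of 67 genes of the histone clusters were lower by 2-fold in both. Removal of the trend in GC content and length left the cell cycle median at -1.18 and the histone median at -1.33 against -1.60 in SCID against the line. A difference in poly(A) capture of histone RNA, most of which lacks a poly(A) tail, cannot be told apart for the histone genes (median -1.60), because the table holds no measure of capture. Histone genes are near-identical copies, so values of single members are uncertain. Growth in the mouse against culture, the difference the design names, remains open and untested, and the design does not separate it from cell sorting.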

How the results depend on the processing

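The alternatives chosen only after the table was seen were the median or most extreme transcript, each transcript alone, genes with 1 transcript, coding transcripts, the 1.5-fold threshold, matching on transcript number and the GC and length adjustment. No called value reversed in any alternative run. At 4-fold the counts higher and lower were 0 and 0 for WT against SCID, 16 and 4 for SCID against the line and 26 and 5 for WT against the line; at 1.5-fold they were 131 and 21, 1311 and 1121, and 1339 and 994. Counting each transcript, and so more items, gave 718 higher for SCID and 774 higher and 367 lower for WT against the line. Whether the number of items accounts for this was not tested. The 2 genes lower in WT than SCID became 5 with the extreme transcript, 5 with each transcript and 0 after the GC and length adjustment. The interferon-gamma median for WT against SCID was 0.87 with the extreme transcript and 0.51 with each transcript, and the macrophage median was 0.82 without Apoe. Against the line, the extreme transcript gave -1.28 for the cell cycle and 0.98 for the hypoxia list in SCID, and each transcript gave 0.99 for the immediate-early list in SCID and 0.87 for the hypoxia and 1.02 for the immediate-early list in WT; the cause was not tested. Centring on the median gene kept 350 of 350 values within 0.1 log2, or counts within 1.5 times, of those reported, and the GC and length adjustment took 87 of 350 beyond that. Among 31 ranked lists, that adjustment gained 3 calls for WT against SCID (TGF-beta targets, matrix genes and fibroblast markers, all lower), and gained 1 (acinar markers, higher) and lost 2 (type I interferon and NF-kB genes) for SCID and lost 1 (basal-like genes) for WT against the line; matching on transcript number moved none. No paired analysis was possible because each group has 1 library. Scalings, pseudocounts, filters on level, removal of abundant genes, counting intervals and mean-count floors were not run for want of counts, and what depth limits is unknown.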

Other observations

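The gene families here were chosen only after the table was seen, and carry no test of conditions. Cathepsins, lysosomal proteases, were above 0 in 10 of 10 measured genes in both tumour pools against the line, with medians of 0.70 in SCID and 0.95 in WT; between the pools 7 of 10 were above 0 in WT against SCID, with a median of 0.22 (percentile 99.99). Of 16 collagens, 10 were higher by 2-fold in SCID and 8 in WT, with medians of 1.17 and 1.09, and the median between the pools was -0.14 (percentile 0.01). Mitochondrial ribosomal proteins (78 genes) had medians of -0.48 and -0.46 against the line, with none above 0 in either pool, and 35 proteasome subunits had -0.45 and -0.42. Cytosolic ribosomal proteins (81 genes) lay nearer to 0, at -0.21 and -0.23.

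Between the tumour pools, 9 of 9 H2 class I genes were above 0 in WT against SCID, with a median of 0.54. H2-K1, H2-D1 and H2-T23 of this family are also in the MHC class I list above. Against the line the same family had a median of -0.09 in SCID and 0.49 in WT. The 4 measured interferon-inducible GTPases, all of them members of the interferon-gamma list above, had a median of 1.01 between the pools, and the 4 Toll-like receptors 0.54. The 303 Zfp zinc finger genes had a median of -0.07, with 83 above 0. This family was not adjusted for GC content, with which WT minus SCID had a Spearman correlation of 0.317 across transcripts.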
